A study of Mus musculus with 3 samples.

How the data were processed

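RNA bound to chromatin was measured in bone marrow-derived macrophages of C57BL/6J mice, primary cells grown from marrow and exposed during 40 min to Lipid A (100 ng/ml), the part of bacterial lipopolysaccharide that activates Toll-like receptor 4. The series used here holds 1 group of 3 biological replicates, numbered 1, 2 and 3 as in the labels. Per the labels the replicates are separate biosamples that cite the same donor entry, and the libraries were made from 1 µg, 250 ng and 500 ng of RNA for replicates 1, 2 and 3. An untreated control, another time point or another cell fraction was not analysed here, so levels were compared between genes within each library and between the replicates, and p-values from limma and the sign-flip test measure the spread between these libraries. Those from permuted gene labels or random lists measure the spread between genes within these libraries.

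For each library the authors deposited a gene table with expected counts, TPM and FPKM (abundances scaled for length and sequencing depth), a transcript table with the same columns, and another transcript table with estimated counts and TPM. Per the file headers and the deposited notes, the values refer to genome assembly mm10 and annotation release M21. The first pair of tables was derived from alignments to the transcriptome (the alignment-based tables) and the other directly from the reads (the alignment-free table), per the deposited notes. The programs are not given in the sources used here; the column layouts are those of RSEM and kallisto. Expected counts deposited by the authors are not whole numbers, because reads that match several transcripts were divided between them, and they were rounded before count-based steps. TPM deposited by the authors divides counts by the effective length of each transcript, so a gene shorter than a typical fragment receives a very high TPM from few reads. How strand was treated in counting is not stated, so overlapping genes on opposite strands are uncertain, as are near-identical copies. The tables hold annotated transcripts, and unspliced RNA was not measured separately.

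Identifiers were joined to the reference annotation of the same release. The gene tables held 55536 annotated genes, 26248 tRNA rows, 96 ERCC spike-in rows and 1 phiX row. The last 3 kinds were left out of tests and of the library sizes used for scaling. Total expected counts, and shares given as percent of them, cover all rows, these 3 kinds included. Total expected counts were 12699813, 18280033 and 18087091 in replicates 1, 2 and 3. Molecular identifiers are not named in the sources used here, so binomial intervals and floors cover counting error only. A count of 0 allows a share of up to 2.36e-05%, 1.64e-05% and 1.66e-05% in replicates 1, 2 and 3, taken as 3 counts of the total.

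Levels were analysed as log2(TPM + 0.1), which understates differences of genes near 0. Each value was set against the reference gene, defined as the library's median over 8764 nuclear protein-coding genes with a mean TPM of at least 1. For 18472 genes with a mean TPM of at least 0.1 or on a list, limma's treat method with a trended prior variance tested whether the level lay more than 2-fold above or below that reference, two-sided, with Benjamini-Hochberg adjustment over all genes tested and over each list alone. A gene with an adjusted p under 0.05 is called higher or lower. List medians were compared with 10000 random lists of the same size drawn from protein-coding genes with a mean TPM of at least 0.1. Early and late response lists were compared by the difference of their medians in each library, with an exact sign-flip permutation test over the libraries and a permutation of gene labels with 100000 resamples, adjusted over the 4 differences.

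Spread between replicates was measured on rounded expected counts with edgeR (TMM scaling, filterByExpr with a minimum count of 10, log2 CPM with a prior count of 2, common dispersion). For each list with at least 5 expressed members the median SD and each library's median deviation from the mean of the 3 libraries were set against 10000 random lists matched on mean log2 CPM in 20 bins. The deviations formed a family of 33 tests over 11 lists. The retained-intron share is the percentage of a gene's transcript TPM in isoforms annotated as retained intron, for genes with at least 1 such isoform and 1 protein-coding isoform and a mean TPM of at least 1. Lists were again set against 10000 random lists matched on mean TPM.

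Lists, tests, alternatives and the rule for named genes were set before the data were examined. The lists covered immediate-early genes, early NF-κB targets, interferon and IRF3 targets, secondary response genes, macrophage genes, proliferation, ribosomal proteins, mitochondrial mRNA, nuclear long noncoding RNA, noncoding RNA machinery, spliceosome genes, and markers of 11 other cell types (neutrophil, T cell, B cell, NK cell, dendritic, mast cell and basophil, erythroid, megakaryocyte, fibroblast, endothelial and adipocyte). Every list member was matched; Rmrp and Rnu3a each name a pair of annotated genes, and the first identifier was used in the lists. The rule named the members of each list with the highest mean TPM, the lowest members of the first 5 lists, a set of genes fixed by name, and the 10 leading genes by protein-coding TPM, by SD of log2 CPM (mean CPM of at least 10) and by retained-intron share (mean TPM of at least 10). Genes named outside that rule are said to be chosen after their values were seen.

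Alternatives were other pseudocounts, the alignment-free table, FPKM, other bands, reference genes and filters, TMM and DESeq2 scaling, DESeq2 dispersions, other list summaries, other isoform classes and leaving out each replicate. Added after seeing the data were class shares without genes of an effective length under 50 bases and a comparison of the quantification tables after centring each on its reference median.

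Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data. In counts simulated for 8765 protein-coding genes with 200 of them set 8-fold from the reference, limma's treat recovered 100% with the right direction and called 4 of 2000 genes placed at the edge of the 2-fold band. All other genes were set to a common level, and all shared a common spread. Calls of genes with few counts or a large spread between libraries were therefore not tested. The common biological coefficient of variation was recovered as 0.218 where 0.219 was set. In simulated log2 CPM of 12931 genes, a list of 36 genes set to deviate by -0.50 in replicate 2 was recovered at -0.49, and 4% of 300 tests of unchanged lists had a p under 0.05. Genes were simulated independently and unchanged lists drawn at random. The 4% therefore does not cover lists whose genes vary together between libraries. For the label permutation, 6.5% of 200 simulated unchanged comparisons had a p under 0.05.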

Results

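Chromatin-associated RNA was profiled by total RNA sequencing after ribosomal RNA depletion in bone marrow-derived macrophages that had been exposed to Lipid A (100 ng/ml) during 40 min before harvest, in 1 group of 3 biological replicates. Total expected counts were 12699813, 18280033 and 18087091 in replicates 1, 2 and 3. At a TPM of at least 1, 8906, 8626 and 8672 protein-coding genes were detected in these libraries, and 8130 in every library. The reference gene, the median of expressed nuclear protein-coding genes, lay at a TPM of 7.57, 6.64 and 6.56. Of all 18472 genes tested, 2782 were called higher than this reference and 9712 lower.

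The series samples a single early time, so the first question was which classes of Lipid A response genes stood high on chromatin at 40 min. Early NF-κB targets held the highest levels of the response lists. Tnfaip2, an NF-κB-inducible gene, had a TPM of 2268 ± 760 (SD, n = 3), the cytokine gene Il1b 774 ± 245, Tnfaip3, which encodes the NF-κB inhibitor A20, 765 ± 155, and the chemokine gene Cxcl2 587 ± 147. Nfkbia, which encodes IκBα, stood at 422 ± 30.3, and Tnf at 350 ± 112, which is 5.59 ± 0.18 (SE) log2 units above the reference gene (adjusted p = 4.6e-05, limma treat with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Of 58 list members 53 were higher than the reference gene by more than 2-fold, 3 were lower (Cxcl3, Gpr84 and Lif, the last chosen after its values were seen) and 2 were neither, with the same counts adjusted over the list alone. Cxcl3 had a TPM of 0.267 ± 0.0896. The list median was 7.23 ± 0.30 in log2(TPM + 0.1), above all of 10000 random lists of protein-coding genes (percentile 100).

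Tnfaip2 (identifier ENSMUSG00000021281.15) lies on chromosome 12 at 111442469 to 111455018 (mm10, plus strand), with 12 exons in its longest annotated transcript. Tnf (ENSMUSG00000024401.14) lies on chromosome 17 at 35199381 to 35202007 on the minus strand, Cxcl2 (ENSMUSG00000058427.10) on chromosome 5 at 90903871 to 90905938 on the plus strand, and Nfkbia (ENSMUSG00000021025.8) on chromosome 12 at 55489410 to 55492647 on the minus strand. The Tnf value rested on 9342, 8165 and 9504 expected counts in replicates 1, 2 and 3.

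Immediate-early genes were also high, at lower levels. Dusp1, a phosphatase gene acting on MAP kinases, had a TPM of 335 ± 67.1, Mcl1 291 ± 100, Klf6 254 ± 84.4 and Atf3 123 ± 44.7 (SD, n = 3). Fos stood at 36.8 ± 11.0 and Egr1 at 45.7 ± 15.8, or 2.36 ± 0.20 and 2.65 ± 0.17 (SE) log2 units above the reference gene (adjusted p = 0.0010 and 0.00036, limma treat with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Of 30 members 22 were higher, 3 lower (Fosl1, Nr4a2 and Plk3, the last chosen after its values were seen) and 5 neither, again with the same counts adjusted over the list alone. Fosl1 had a TPM of 0.300 ± 0.265. The list median was 5.02 ± 0.05, also at percentile 100 of random lists. This percentile is not particular to response genes. The spliceosome list, with a median of 5.37, also lay at percentile 100, and ribosomal protein genes lay at 99.99. With a band of 4-fold 14 members were higher, and with reference genes from a TPM of 5, 12; Fos was then not called (adjusted p = 0.1321 and 0.2861, limma with Benjamini-Hochberg adjustment, 2.36 and 1.16 log2 units above the reference).

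The median level of interferon and IRF3 target genes lay between those of these early lists and the secondary response genes. Gbp5, which encodes a guanylate-binding protein, had a TPM of 212 ± 136, Rsad2, which encodes viperin, 96.5 ± 44.8, and Ifih1, which encodes the RNA sensor MDA5, 70.6 ± 41.6 (SD, n = 3). Ifnb1, which encodes interferon-β, stood at 6.87, 0.700 and 3.74 in replicates 1, 2 and 3, on 51, 8 and 41 expected counts, at -1.34 ± 0.57 (SE) log2 units from the reference gene, which did not pass the test (adjusted p = 0.39, below it in 3 of 3 libraries, limma treat with Benjamini-Hochberg adjustment). The chemokine gene Cxcl10 stood at 82.3, 10.2 and 37.8, 2.18 ± 0.52 (SE) log2 units above the reference (adjusted p = 0.053 by the same limma test with Benjamini-Hochberg adjustment, above it in 3 of 3 libraries, and 0.0018 without replicate 2, at 2.97). Of 36 members 14 were higher, 3 lower (Cxcl9, Cxcl11 and Isg20, the last chosen after its values were seen) and 19 neither; adjusted over the list alone, 13 were higher. The list median was 4.04 ± 0.71, at percentile 99.99. Without a band 22 members were higher, and without replicate 2, 20.

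Secondary response genes were mostly low. Il6 had a TPM of 1.36, 0.150 and 0.890 in replicates 1, 2 and 3 on 40, 7 and 40 expected counts, and Nos2, which encodes inducible nitric oxide synthase, 0.117 ± 0.0153 (SD, n = 3). Il33 and Ido1 had 0 counts in every library, which allows up to 3 counts of each library's total. The cytokine subunit gene Il12b stood at 13.1, 1.52 and 9.45 in replicates 1, 2 and 3 and did not pass the test against the reference gene. Of 36 members 25 were lower, 8 neither and 3 higher, with the same counts adjusted over the list alone. A low level was common, with 9712 of all 18472 genes tested called lower. The higher members were Acod1, which encodes the itaconate-producing enzyme, at 94.4 ± 63.9, the complement gene C3 at 61.2 ± 10.4 and the cytokine gene Il15 at 40.9, 17.9 and 34.4 in replicates 1, 2 and 3. The list median was -0.88 ± 0.33, below all random lists (percentile 0). Random lists held only genes with a mean TPM of at least 0.1, while list members below that, such as Il33 and Ido1, were kept. The percentile may therefore overstate how low the list stood. Of the members with a mean TPM of at least 1, 3 were lower, as fewer members were tested.

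**Figure D1:**
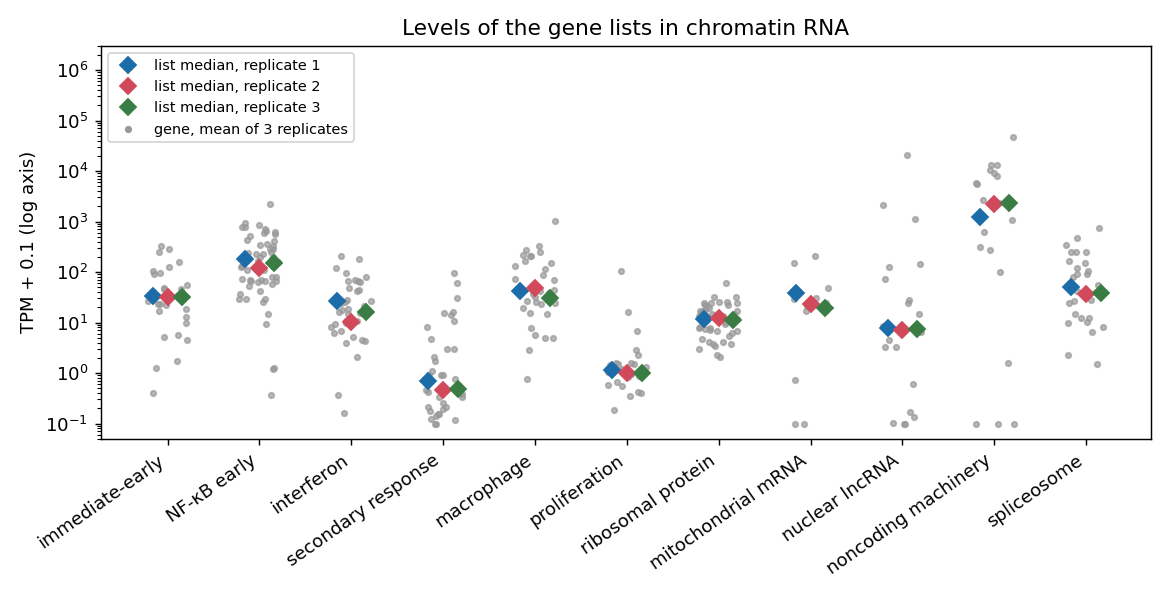
Mean TPM plus 0.1 of each gene over the 3 replicates (grey points, log axis) and the list median in each replicate (diamonds) for 11 gene lists. The NF-κB list has medians of 184, 121 and 150 TPM in replicates 1, 2 and 3, and the secondary response list 0.610, 0.370 and 0.390.

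Set against each other, both early lists stood above the secondary response list in every library. The median of the NF-κB list exceeded that of the secondary list by 8.11 ± 0.14 log2 units (SD, n = 3; permutation of gene labels, p = 1e-05, Benjamini-Hochberg adjusted p = 1.3e-05, positive in 3 of 3 libraries), and that of the interferon list by 3.18 ± 0.41 (p = 1e-05, Benjamini-Hochberg adjusted p = 1.3e-05 by the same permutation, positive in 3 of 3 libraries). The immediate-early list exceeded the secondary list by 5.90 ± 0.27 (permutation p = 1e-05, Benjamini-Hochberg adjusted p = 1.3e-05, positive in 3 of 3 libraries); 1e-05 is the smallest value these permutations can give. Its difference from the interferon list was 0.31, 1.64 and 0.97 in replicates 1, 2 and 3, with a mean of 0.97 ± 0.67, positive in 3 of 3 libraries, and did not pass the test (permutation p = 0.0504, Benjamini-Hochberg adjusted p = 0.0504). Leaving out replicate 1 or replicate 3 gave 1.30 and 0.97 with Benjamini-Hochberg adjusted permutation p of 0.0215 and 0.0452, and leaving out replicate 2 gave 0.64 and 0.2539. The same difference was 0.41 in the alignment-free table, 0.76 with list means and 0.95 for members with a mean TPM of at least 0.1. None of these passed (Benjamini-Hochberg adjusted permutation p = 0.4313, 0.184 and 0.0919). Over the libraries the exact sign-flip test gave a two-sided p of 0.25 for each difference, the smallest that 3 libraries allow. These lists group genes by what is known of their timing, and a change with Lipid A was not measured.

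**Figure D2:**
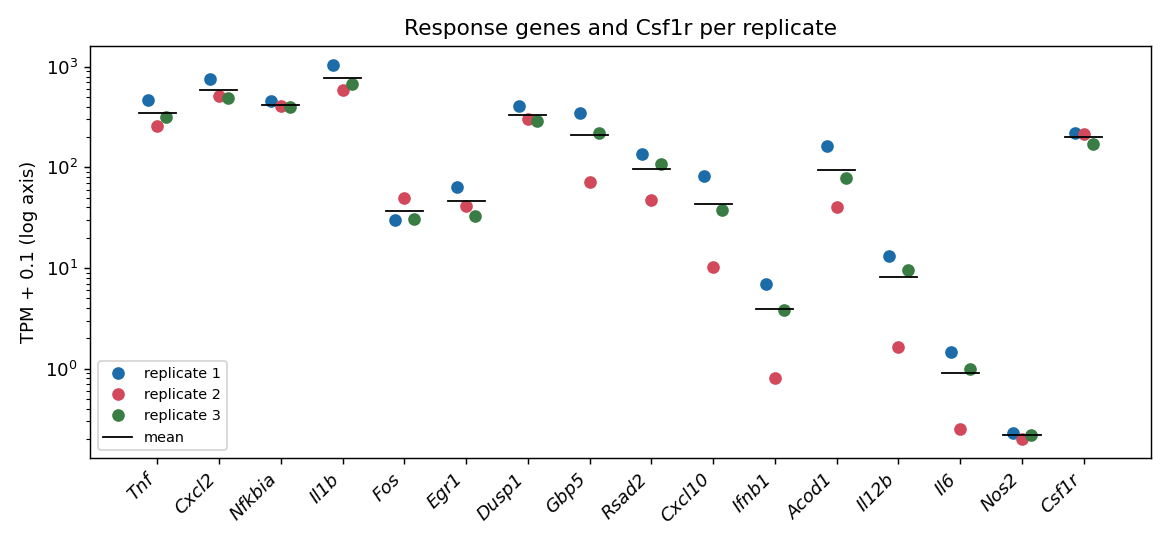
TPM plus 0.1 (log axis) of response genes and the macrophage gene Csf1r in each of the 3 replicates, with the mean as a line. Cxcl10 lies at 82.3, 10.2 and 37.8 TPM in replicates 1, 2 and 3, while Nfkbia lies at 457, 409 and 401.

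Macrophage genes were present at high level. Sirpa, which encodes an inhibitory receptor of myeloid cells, had a TPM of 1005 ± 226, the leukocyte phosphatase gene Ptprc 329 ± 139, the protease gene Ctsb 276 ± 53.9 and Csf1r, the receptor for macrophage colony-stimulating factor, 203 ± 27.3 (SD, n = 3). Csf1r lay 4.85 ± 0.13 (SE) log2 units above the reference gene (adjusted p = 3.9e-05, limma treat with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Of 32 members 24 were higher, 1 lower (Cebpa, 0.660 ± 0.417) and 7 neither, with the same counts adjusted over the list alone. The list median was 5.30 ± 0.33, at percentile 100. With a band of 4-fold, or with reference genes from a TPM of 5, 15 members were higher, and 2 members were lower without replicate 2.

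Markers of 11 other cell types were mostly at or near 0. Of 92 markers 86 were lower than the reference gene, 5 neither and 1 higher, and 84 had a mean TPM below 1. The exception was Vwf, an endothelial and megakaryocyte gene, at 49.3 ± 3.51 (SD, n = 3) on 2057, 4697 and 4627 expected counts. Lower markers were 8 of 10 for T cells, 9 of 10 for erythroid cells, 5 of 7 for megakaryocytes and 6 of 7 for endothelium, and every marker of the neutrophil, B cell, NK cell, dendritic, mast cell and basophil, fibroblast and adipocyte lists was lower. In the alignment-free table the leading NK cell and dendritic markers, Klre1 and Ccr9, were not called (adjusted p = 0.624 and 0.9936, limma treat with Benjamini-Hochberg adjustment). Ccr9 was also not called with a band of 4-fold or with reference genes from a TPM of 0.1. The leading markers of 3 of these lists were Treml1 at 8.67 ± 1.39, Cd5 at 5.48 ± 1.21 and Alas2 at 3.38 ± 0.545. Highest of the neutrophil markers was Mmp8 at 0.270 ± 0.0819, and of the fibroblast markers Col1a1 at 0.370 ± 0.321. Of 28 proliferation genes 24 were lower, 3 neither and 1 higher (Mki67, at 107 ± 32.2), with the same counts adjusted over the list alone. Of 30 spliceosome genes 21 were higher, led by Hnrnpa2b1 at 730 ± 116, 2 lower and 7 neither, again with the same counts adjusted over the list alone.

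The protein-coding genes with the highest TPM included, beside Tnfaip2, Lilrb4a at 2093 ± 640, Lilr4b at 2036 ± 576, Ifrd1 at 1893 ± 436, Gpnmb at 1063 ± 153, Zeb2 at 1017 ± 328 and Rbm39 at 927 ± 166 (SD, n = 3). Lilrb4a and Lilr4b are neighbouring and closely related genes, so the division of reads between them is uncertain. The nuclear noncoding RNA Malat1 had a TPM of 21138 ± 7122 and took 9.14% ± 1.36 of expected counts, and Neat1, the scaffold RNA of paraspeckles, had a TPM of 2103 ± 243. Of 20 nuclear long noncoding RNAs 8 were higher, 6 lower and 6 neither. Of 20 noncoding RNAs of the cell's machinery 16 were higher and 4 lower, led by Rmrp at 48108 ± 14609, which overlaps another annotated gene of the same name. Rmrp had an effective length of 66.0 bases and took 0.365% of expected counts. Division by so short a length raises TPM, so levels of short RNAs are not comparable with those of long genes. Of 50 ribosomal protein genes 14 were higher, 2 lower and 34 neither, and of 13 mitochondrial mRNAs 8 were higher, 3 lower and 2 neither; adjusted over the list alone, 12 ribosomal protein genes were higher and the other counts of these 4 lists were the same. The lower mitochondrial genes were mt-Co2 and mt-Nd3 at 0 and mt-Co3 at 0.617, chosen after their values were seen, beside mt-Co1 at 204 ± 134; none was lower in the alignment-free table, where 2 machinery RNAs and 0 ribosomal protein genes were lower. With a band of 4-fold 1 ribosomal protein gene and 3 mitochondrial mRNAs were higher, and without a band 31 ribosomal protein genes.

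The share of each RNA class depended on the unit. Protein-coding genes took 61.7% ± 2.56 of expected counts and 21.4% ± 2.94 of TPM (SD, n = 3). Long intergenic noncoding RNA took 30.7% ± 3.38 of counts and 8.85% ± 1.45 of TPM. Small nucleolar RNA took 43.0% ± 3.04 of TPM and 0.358% ± 0.0284 of counts, and small nuclear RNA 12.3% ± 4.08 of TPM and 0.203% ± 0.0735 of counts. A single gene annotated as long intergenic RNA, Gm26917, on chromosome 17 at 39843013 to 39846341, took 14.9% ± 3.85 of counts. It was chosen after its values were seen. It lies beside CT010467.1, annotated as ribosomal RNA, so its reads may be ribosomal RNA. The class shares follow the annotation and do not settle this.

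**Figure D3:**
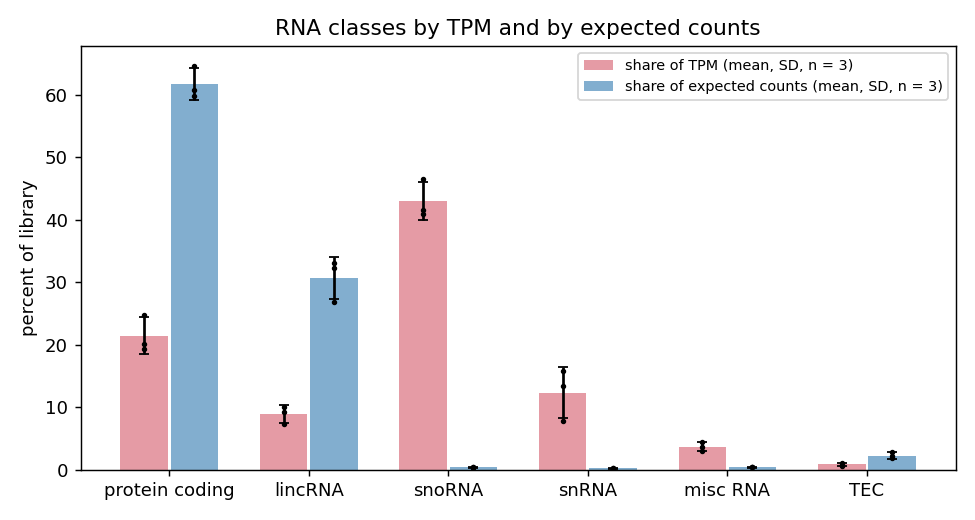
Share of each library held by 6 RNA classes, as percent of TPM and as percent of expected counts (bars, mean; error bars, SD; points, the 3 replicates). Small nucleolar RNA takes 43.0% of TPM and 0.358% of counts, and protein-coding genes 21.4% and 61.7%.

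The replicates were then compared. Across 18368 genes, Pearson's r of log2(TPM + 0.1) was 0.914 for replicates 1 and 2, 0.923 for 1 and 3 and 0.933 for 2 and 3, and Spearman's rho 0.916, 0.925 and 0.930; genes are not independent replicates. The common biological coefficient of variation from edgeR was 0.219 over 12931 genes.

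Interferon genes differed most between replicates among the response lists. Their median SD of log2 CPM was 0.51, against 0.24 in random lists of like level (adjusted p = 0.0011 by comparison with random lists, Benjamini-Hochberg over 11 lists), and the NF-κB list had 0.29 against 0.22 (adjusted p = 0.0368, and 0.9415 without replicate 2). In replicate 2 the interferon list deviated by -0.52 from the mean of the libraries, with 30 of 33 expressed members below it, and in replicate 1 by 0.43 and 5 of 33 below (adjusted p = 0.0006 for both by the same comparison, Benjamini-Hochberg over 33 tests, from an unadjusted 0.0002, the smallest these lists can give). The NF-κB list deviated by -0.28 in replicate 2 and 0.21 in replicate 1, and the macrophage list by 0.26 in replicate 2 and -0.16 in replicate 1 (adjusted p = 0.0006, 0.0006, 0.0006 and 0.0278 by the same comparison with Benjamini-Hochberg adjustment). Of 58 NF-κB members 47 lay below the mean in replicate 2, and of 32 macrophage members 5. In replicate 3 the NF-κB list deviated by 0.09 and the macrophage list by -0.14 (adjusted p = 0.0038 and 0.0006 by the same comparison with Benjamini-Hochberg adjustment; 11 of 58 and 24 of 32 below the mean), and the interferon list by 0.08, which did not pass (adjusted p = 0.0714, Benjamini-Hochberg) but did on log2(TPM + 0.1), at 0.10 (adjusted p = 0.0214). Replicate 2 was the library made from 250 ng of RNA, and TEC genes, a class of annotated transcripts awaiting experimental support, deviated by 0.23, -0.22 and -0.00 in replicates 1, 2 and 3. The immediate-early list deviated by 0.06, -0.02 and 0.07 in replicates 1, 2 and 3, which did not pass the test. Deviations from the mean of a pair of libraries depended on the library left out. Without replicate 3 those in replicate 1 were 0.51 for the interferon, 0.25 for the NF-κB and -0.20 for the macrophage list, further from 0 than with 3 libraries; without replicate 2 those in replicate 1 were 0.20 for the interferon, 0.06 for the NF-κB and -0.00 for the macrophage list, the last not passing the test, and without replicate 1 those in replicate 2 were -0.28, -0.19 and 0.15 and those in replicate 3 the same with the opposite sign. Without replicate 2 the deviations in replicate 3 were -0.20, -0.06 and 0.0048, each opposite in sign to that of 3 libraries and the last not passing. The interferon SD was 0.40, 0.32 and 0.72 without replicates 1, 2 and 3. Among single genes the SD of log2 CPM was 1.43 for Cxcl10, 1.53 for Il12b and 1.34 for Ifit1, each lowest in replicate 2.

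Other lists deviated as well. Mitochondrial mRNA deviated by 0.53 in replicate 1 and -0.40 in replicate 3, ribosomal protein genes by -0.22 in replicate 1, and noncoding RNAs of the machinery by -0.52 in replicate 1 (adjusted p = 0.0006 for each by comparison with random lists, Benjamini-Hochberg over 33 tests; below the mean in 43 of 50 ribosomal and 12 of 15 machinery members of replicate 1, and in 9 of 9 mitochondrial members of replicate 3). Their median SD was 0.50 for mitochondrial mRNA and 0.51 for noncoding machinery, against 0.25 and 0.23 in random lists (adjusted p = 0.0059 and 0.0011 by the same comparison, Benjamini-Hochberg over 11 lists), and 0.16 and 0.25 without replicate 1, where neither passed; without replicate 3 that of mitochondrial mRNA was 0.47 and did not pass. Noncoding RNAs of the machinery also deviated by 0.22 in replicate 3, and ribosomal protein genes by 0.13 in replicate 2 and 0.11 in replicate 3 (adjusted p = 0.0006, 0.0374 and 0.0081 by the same comparison, Benjamini-Hochberg over 33 tests; 4 of 15, 15 of 50 and 15 of 50 members below the mean). These deviations did not pass without replicate 1, at -0.05, 0.02 and -0.02, and that of ribosomal protein genes in replicate 3 not on log2(TPM + 0.1), at 0.04 (adjusted p = 0.4743). Nor, without replicate 1, did that of mitochondrial mRNA in replicate 3, at -0.11 (adjusted p = 0.2181, Benjamini-Hochberg). In replicate 2 the machinery list deviated by 0.17 and mitochondrial mRNA by -0.15, which did not pass with 3 libraries (adjusted p = 0.0876 and 0.3156 by the same comparison with random lists). Without replicate 3 that of mitochondrial mRNA in replicate 2 was -0.33 and passed (adjusted p = 0.0114 by the same comparison). The deviations of the proliferation, spliceosome, nuclear long noncoding and secondary response lists did not pass in any library on log2 CPM of the filtered genes. Some passed in other settings (Benjamini-Hochberg adjusted p from the same comparison with random lists): proliferation in replicate 1 without a filter, at -0.21 (adjusted p = 0.0255), and without replicate 2, at -0.13 (0.0418); nuclear long noncoding RNA in replicate 3 without a filter, at 0.13 (0.0477), and without replicate 1, at 0.16 (0.0467); and the secondary response list in replicate 1 on log2(TPM + 0.1), at 0.27 (0.0071), and without replicate 2, at 0.12 (0.0424). The gene with the largest SD was Zbed6 at 2.17. It has 1 annotated exon and lies within the bounds of Zc3h11a (chosen after its values were seen) on the same strand of chromosome 1, at 133655879 to 133660885, so the division of reads between the pair is uncertain.

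**Figure D4:**
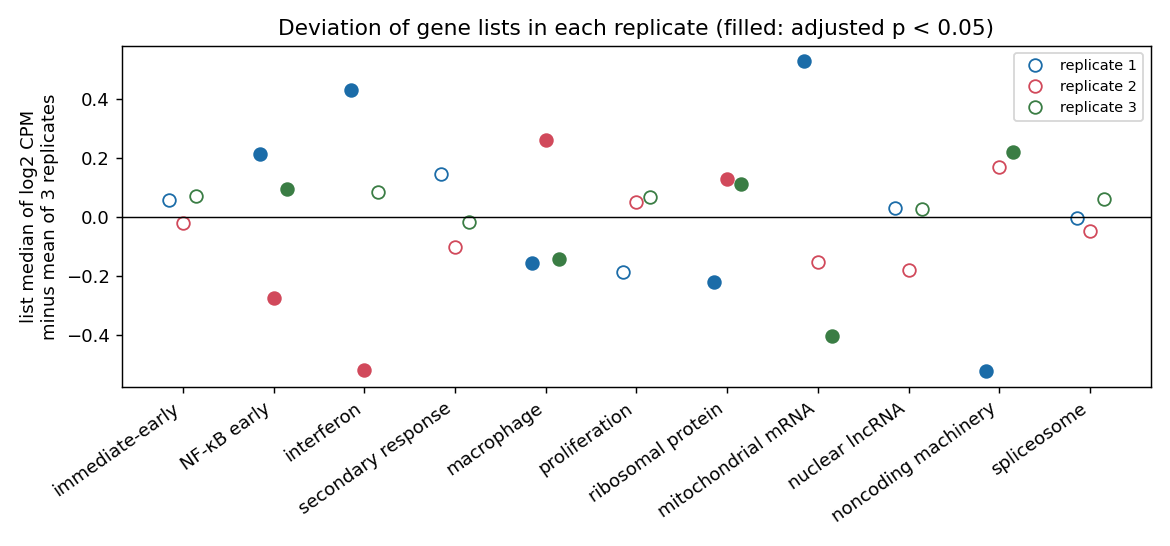
Median deviation of log2 CPM from the mean of the 3 replicates, in each replicate, for 11 gene lists (filled points, adjusted p under 0.05 against random lists of like level; open points, not). The interferon list lies at 0.43, -0.52 and 0.08 in replicates 1, 2 and 3, and the immediate-early list at 0.06, -0.02 and 0.07.

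Transcripts annotated with a retained intron took a large share of the signal. Only annotated isoforms were quantified, and unspliced RNA was not measured separately. The share therefore does not tell retained introns from introns not yet removed. Over 5826 genes the median share was 40.2% ± 2.38 (SD, n = 3), and in 2030 genes it was over 50%. Slc27a1, a fatty acid transporter gene, had 99.3% ± 1.00 of its TPM in such isoforms and Dusp1 95.7% ± 1.39, while Csf1r had 8.49% ± 3.25. Ribosomal protein genes had a list share of 64.6% ± 3.86, against a median of 39.8% in random lists of like level (adjusted p = 0.0014 by comparison with random lists, Benjamini-Hochberg over 7 lists). With the alignment-free table their share was 56.8% and did not pass (adjusted p = 0.096 by the same comparison with Benjamini-Hochberg adjustment). The NF-κB list at 54.6% ± 3.13 and the interferon list at 48.9% ± 4.61 did not pass the test (Benjamini-Hochberg adjusted p = 0.6434 for both by the same comparison), nor did the other 4 lists.

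The quantification tables were compared last. Across 28885 genes the alignment-based and alignment-free TPM had a Spearman's rho of 0.593 ± 0.00982 and a Pearson's r of 0.665 ± 0.00787 (SD, n = 3 libraries), and across 15640 protein-coding genes a Spearman's rho of 0.848 ± 0.00802. Of 353 members of the pathway lists, 44 were more than 2-fold higher in the alignment-free table in every library and 4 more than 2-fold lower. Lgals3 had a TPM of 214 in the alignment-based table and 2046 in the alignment-free one, and Plek 952 and 2447. After each table was centred on its own reference median, an alternative added after seeing the data, these counts were 27 and 12.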

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

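The tests of transcript GC and length, unspliced RNA, depth, starting RNA, later response genes, opposite-strand overlap and effective length were chosen after the results were seen; the test of shared 31-mers was chosen before its result was seen.

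Reads were counted in features outside the main measurement, above the 3 counts that a count of 0 allows. The phiX sequence, a bacteriophage genome used as a sequencing control, held 159765, 40768 and 36158 expected counts in replicates 1, 2 and 3, or 1.26% (95% Wilson interval 1.25% to 1.26%), 0.223% (0.221% to 0.225%) and 0.200% (0.198% to 0.202%). The tRNA entries held 25, 20 and 18 counts. The ERCC spike-in entries of the alignment-free table held 9, 29 and 50 estimated counts, while those of the alignment-based gene table held none.

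Interferon genes were lower in replicate 2, by a median deviation of -0.52. Random lists matched on level, transcript GC and length left an excess of -0.48, with the list below all 10000 of them, which argues against GC or length bias. Lists of TEC genes, taken to stand for unspliced RNA, had a mean deviation of -0.26 and left an excess of -0.25. The median retained-intron share over 5826 genes was 42.9%, 38.8% and 38.8% in replicates 1, 2 and 3, so by that measure replicates 2 and 3 were alike. Less unspliced RNA in replicate 2 is left open, because unspliced RNA at the interferon genes was not measured. Replicates 2 and 3 had nearly equal depth (ratio 1.01) and the list's median difference between them, replicate 2 minus replicate 3, was still -0.56, beyond all 10000 matched lists, which argues against depth. The amount of starting RNA cannot be told apart from the replicate, because each library had its own amount. With 1 µg, 500 ng and 250 ng the interferon list deviated by 0.43, 0.08 and -0.52 and the NF-κB list by 0.21, 0.09 and -0.28. Both followed the order of the amounts. The macrophage list ran in the reverse order, at -0.16, -0.14 and 0.26. Mitochondrial mRNA (0.53, -0.40 and -0.15) and noncoding machinery (-0.52, 0.22 and 0.17) followed neither order. The design names no biological difference between the replicates, and a test of later response genes (difference 0.17) decided nothing.

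With at least 10 reads in the alignment-free table, 6500 genes had over 16-fold more reads there than in the alignment-based gene table, 40.0% of them protein-coding and 19.1% long intergenic noncoding. The share of their 31-mers found in other genes had a median of 3.83%, which is 2.33 percentage points above genes of like level within 2-fold. That difference, beyond all 1000 matched draws, is under the 5 points set beforehand, which argues against shared sequence between annotated genes as the main cause. Of these genes 31.7% overlapped an annotated gene on the opposite strand. This was less often than in matched genes, with a difference of -13.9 percentage points, beyond all 1000 draws. It argues against annotated genes on the opposite strand as the source for most of them. Matching was on level and not on class or length. Unannotated RNA of the opposite strand was not covered, so the treatment of strand stays open. The cause stays open, and no biological explanation was tested.

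Small nucleolar RNA took 43.0% of TPM. Genes with an effective length under 50 bases held 97.5% of that TPM. Only 3 of 1507 genes of the class had a longer effective length, so this share was largely fixed by class membership. The class took 0.358% of expected counts, so its high share of TPM arose in the division by effective length. Without such genes, an alternative added after seeing the data, the class took 2.40% of TPM. That value rests on the 3 genes left and adds no separate support. No biological explanation was tested.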

How the results depend on the processing

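Class shares without short genes were chosen after seeing the data, as was centring of the tables; all other alternatives were planned. No paired analysis was possible because the series holds 1 group. A value was taken as kept if its direction and side of the threshold stayed or it lay within its spread. Counts of list members were taken as kept within a factor of 1.5, a wide bound for small counts. Across alternatives and left-out replicates, 356 values of the main results were kept, 45 moved, 9 newly passed a test, 3 no longer passed and 3 reversed. For the other lists these were 289, 41, 10, 5 and 3. Both early lists exceeded the secondary list in every alternative, by 4.34 to 6.16 for immediate-early and 6.70 to 8.38 for NF-κB genes. No named gene of 106 reversed. Except where stated, the cause was not tested.

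Shares depended on the unit: with expected counts, long intergenic RNA took 30.7%, protein-coding genes 61.7%, small nuclear RNA 0.203% and small nucleolar RNA 0.358%, and in the alignment-free table they took 10.9%, 33.2%, 5.62% and 8.15%. Without genes of an effective length under 50 bases these were 19.3%, 47.4% and 2.40% for long intergenic, protein-coding and small nucleolar RNA, and 0% for small nuclear RNA. Of the small nucleolar RNA genes 3 of 1507 were left, and of the small nuclear RNA genes 0 of 1385. In the alignment-free table microRNA took 24.1% ± 13.0 of TPM (SD, n = 3), against 0.0206% in the alignment-based gene table. Over a 4-fold difference 20 list members lay apart between the tables.

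The alignment-free table gave list medians of 4.89 (immediate-early), 5.88 (macrophage), 7.70 (NF-κB) and 0.55 (secondary), FPKM 5.24 for immediate-early genes and a pseudocount of 1 0.54 for secondary genes. Counts of higher members, by construction, followed the band and the reference: 14 immediate-early and 15 macrophage genes with a band of 4-fold, 12 and 15 with reference genes from a TPM of 5, 22 interferon and 7 secondary genes without a band, and 24 and 7 with reference genes from a TPM of 0.1. Lower members were 1 immediate-early and 1 NF-κB gene both with a band of 4-fold and with reference genes from a TPM of 0.1; 6 immediate-early, 7 interferon and 5 macrophage genes with reference genes from a TPM of 5; 5 interferon and 4 macrophage genes without a band; and 1 interferon gene in the alignment-free table. With genes tested from a TPM of 1, fewer genes were tested, and 1 interferon, 0 macrophage and 3 secondary genes were lower. Leaving out a replicate gave 1 to 2 lower macrophage genes.

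The interferon deviation in replicate 3 was 0.10 on log2(TPM + 0.1) and 0.11 without a filter, and the secondary list had 0.27 in replicate 1 on log2(TPM + 0.1) and an SD of 0.49 without a filter; each then passed. Leaving out a replicate gave, from lowest to highest, interferon -0.20 to 0.28, NF-κB -0.0597 to 0.19, macrophage -0.15 to 0.0048 and secondary -0.12 to -0.0068 in replicate 3, macrophage -0.20 to -0.0048 and secondary 0.12 to 0.14 in replicate 1, an NF-κB SD of 0.15 to 0.36, and an immediate-early minus interferon difference of 0.64 to 1.30. Replicate 3 reversed without replicate 2 for the interferon (-0.20), NF-κB (-0.0597) and macrophage (0.0048) lists, since with 2 libraries the deviations mirror each other. Also reversed, without replicate 1, were the mitochondrial SD against random lists (0.16; up to 0.68 without another replicate) and the deviations in replicate 3 of the noncoding machinery (-0.0499; up to 0.38) and of ribosomal protein genes (-0.0210; up to 0.14).

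Pearson's r between replicates was 0.971 without a filter and 0.914 to 0.933 leaving out a replicate, and the biological coefficient of variation 0.177 to 0.267. The retained-intron share was 46.7% with processed transcripts added, and that of ribosomal protein genes 56.8% in the alignment-free table. Depth limits genes with few counts in every library, such as Nos2 with 7, 6 and 10 expected counts in replicates 1, 2 and 3.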

Other observations

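The tests of later response genes were chosen after their results were seen. Genes of the chromosome 17 locus that holds Gm26917 were chosen after their values were seen. Gm42418 took 1.62% ± 0.628 of expected counts (SD, n = 3), and CT010467.1, annotated as ribosomal RNA on the opposite strand and overlapping Gm42418, had 33862, 280361 and 227695 expected counts in replicates 1, 2 and 3. Gm26917 and Gm42418 are counted as long intergenic RNA in the class shares. Their reads were not told apart from ribosomal RNA. The X-inactivation RNA Xist had a TPM of 1130 ± 33.9.

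By class, 314 long intergenic noncoding genes had a median deviation of log2 CPM of 0.22, -0.19 and 0.02 in replicates 1, 2 and 3, 27 small nuclear RNAs 0.67, -0.77 and 0.10, and 46 small nucleolar RNAs -0.50, 0.36 and -0.01, without a test. In the same libraries 10185 protein-coding genes deviated by -0.05, 0.04 and 0.02.

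A hypothesis is that later genes of the Lipid A response were less advanced in replicate 2. The first comparison tried, of the interferon list (-0.52) with the immediate-early list (-0.02), was dropped because the low interferon list had prompted the hypothesis. The second set the secondary response list (-0.10, 13 of 19 expressed genes below the mean) against the early NF-κB list (-0.28, 47 of 58), and the difference of 0.17 went against the hypothesis (two-sided permutation of gene labels, p = 0.0457). By the same permutation test it was 0.08 on log2(TPM + 0.1) (p = 0.4257) and 0.12 without replicate 3 (p = 0.1114), and 0.23 without a filter (p = 0.0086) and 0.20 without replicate 1 (p = 0.0044). Secondary members went both ways, with Il12b at -1.77, Acod1 at -0.88 and Mmp14 at 0.35, and 25 of the 36 listed genes were lower than the reference gene, so the hypothesis stays open.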
